A study of Mus musculus with 2 samples.

How the data were processed

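Total RNA was extracted with Trizol, purified with RNeasy columns, amplified to antisense RNA and coupled to an NHS ester dye (Cy5), per the labels' protocols. It was hybridised to the Phalanx Mouse Whole Genome OneArray v2, a 1-colour oligonucleotide array, per the labels. The values deposited by the authors are normalised probe intensities on a linear scale, not logarithms. The scanner, the background correction, the normalisation and any filter on probes are not given in the sources used here. The values themselves ran from 15 and 16 to 65495 and 65494, and both columns had nearly the same quantiles, with medians of 304 and 305 and 75th percentiles of 1368 and 1372. Every value was a multiple of 1/18 within a tolerance of 0.001, and the 1000 dimmest probes of a column shared 29 and 40 distinct values. Such equal quantiles would result from a normalisation between arrays, which would remove any difference between the samples in total signal and in the shape of the distribution. Whether a column holds 1 scanned array or a mean of several was not settled, and how the 3 replicates named in the design text of the series relate to the columns is not given in the sources used here. The design text calls one sample PEG cells, and that name was read here as the small-molecule-generated cells because the other is the parental sample.

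Gene symbols came from the annotation of the platform and were brought up to date through Entrez identifiers with a RefSeq gene table (assembly GRCm38.p6), used for names only. Of 13989 probes, 12380 had 1 symbol, 0 had several and 1609 were not listed in the annotation and stayed unnamed. Of the named probes, 12364 matched through the identifier and 16 kept the platform's name. Intensities were brought to log2, and the probes of a gene were averaged on that scale, which gave 11484 genes, 10634 with 1 probe and 850 with 2 or more. Positions in the genome were not used here, because no genome build was named.

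The small-molecule-generated cells were compared with the parental cells. With 1 sample per group no test between groups was possible and no p-value was computed, and the number of arrays limits the precision. Genes above the 25th percentile of the column (93.8 in the parental cells and 93.4 in the small-molecule-generated cells) in at least 1 sample were counted by size, at a difference of 2-fold or more. A gene under that floor in both samples was called dim and given no fold. Where 1 value lay under the floor, the fold is a lower bound, the brighter value over the floor of the other column. As a measure of probe error, the log2 differences of 2 probes of the same gene were compared in 612 genes. The SD of 1 probe around its gene was 1.05, and the correlation between probes was 0.545. That error covers differences between probes on the same 2 arrays and not differences between cultures.

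A set of 42 gene lists was fixed before the data were examined, with 742 memberships, 402 of them measured. For each list the median log2 difference was placed among those of 10000 random lists of the same size, matched on mean intensity in 20 bins, and a list was said to stand apart outside the middle 95% (percentiles 2.5 and 97.5). Of the 42 lists 9 lay above and 9 below that range, where 2.10 in all would lie outside it if genes varied independently. Some lists share members, such as Sox2 and Fbxo15, and genes of a list may vary together. The number outside the range therefore does not measure a departure from chance. The percentile describes these 2 samples and is not a test between conditions. The genes named in the report followed a rule made at the same time. It took the 12 highest and the 12 lowest genes above the floor in both samples, the 5 largest differences each way between the floor and values above the median, 26 genes fixed by name, and up to 2 members each way per list. Of the 26 genes, 13 were measured, and Klf4, Myc, Lin28a, Dppa5a, Sall4, Tdgf1, Cdh1, Col1a1, Col1a2, Twist1, Prrx1, Cdkn2a and Tet1 were not analysed here.

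The alternatives were centring on the median, quantile normalisation, centring by lowess (span 0.3), the brightest probe per gene, an offset of 50, other filters on dim genes, a 4-fold size rule, counting probes, 5 bins, matching on the parental value, and leaving out dim list members. Chosen after seeing the data were setting values under the floor to it, centring each of 3 classes of probe identifiers on its own median, and a size rule of 2 SD of the probe error (4.30-fold). The computation was tested on simulated data with 11484 genes, noise of SD 0.3 and 200 planted differences. It recovered 98.0% of those planted at log2 1.5 and 100% of those at log2 3, put 0.062% of unchanged genes past 2-fold, and placed 3% of 100 unchanged lists outside the middle 95%. That noise was chosen to check the computation and is smaller than the probe error of these arrays, so these shares do not describe the data. With noise of the measured SD of 1.05, a simulation added after seeing the data recovered 68.0% of differences planted at log2 1.5 and 99.0% at log2 3. It put 35.0% of unchanged genes past 2-fold. That may overstate the share in these data, because the SD was taken over all genes with 2 probes, changed ones included. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.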

Results

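Gene expression was measured in 2 samples of mouse cells of embryonic origin, both labelled with the strain C57/ICR. The platform was a 1-colour oligonucleotide microarray whose name describes it as whole genome. The parental cells were at passage 1 and grown in medium with fetal bovine serum. The stem cells generated from a small molecule treatment, according to the title of the series, were at passage 5 and grown in embryonic stem (ES) cell medium. The comparison asks how the expression profile of the small-molecule-generated cells differed from that of the parental cells. The design text of the series names 3 replicates per sample, but 1 column of values per sample was analysed here. There was thus no replicate, and every value describes these 2 samples only, whose passage and medium differed together with the treatment. The table held 13989 probes, of which 12380 carried a gene symbol, for 11484 genes. Coverage was partial, with 402 of the 742 memberships of the gene lists measured. For instance, 10 of 20 pluripotency core genes and 8 of 25 fibrillar matrix genes were measured. Median intensity was 304 in the parental cells and 305 in the small-molecule-generated cells, and the values reached 65495 and 65494, close to the ceiling of a 16-bit scanner (65535). The 25th percentile of each sample, 93.8 and 93.4, was taken as the floor under which a gene was called dim. A gene under the floor in 1 sample was given a fold as a lower bound, its brighter value over the floor of the other sample.

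Genes of the pluripotent state were far brighter in the small-molecule-generated cells. Esrrb, an orphan nuclear receptor of the ES cell network, was at 40.6 in the parental cells, under the floor, and at 33968 in the small-molecule-generated cells, at least 362-fold higher. Sox2 was at 265 and 16129, a 60.8-fold difference, and Utf1, a chromatin-associated factor of ES cells, was 107-fold higher (191 and 20475). Fgf4, the growth factor secreted by ES cells, was at least 192-fold higher (39.7 and 18021). In the opposite direction stood genes of mesenchymal cells and their matrix, with Thy1, a surface glycoprotein of fibroblasts, 349-fold lower (40943 and 117) and Eln, which encodes elastin, at least 322-fold lower (30091 and 81.2).

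Of 9766 genes above the floor in at least 1 sample, 2159 (22.1%) were higher by 2-fold or more in the small-molecule-generated cells and 2209 (22.6%) were lower. The other 5398 (55.3%) differed by less than 2-fold, and 1718 further genes were dim in both samples. Across these 9766 genes, which are not independent replicates, log2 intensities of the 2 samples had a Pearson r of 0.704 and a Spearman rho of 0.702. The genes of mesenchyme and pluripotency named above lay far outside the 2-fold lines in the plot of both samples' intensities. The precision of a single probe was limited. Among 612 genes with 2 probes above the floor, the log2 difference of a probe had an SD of 1.05 around its gene, which corresponds to 2.07-fold, and 51.3% of the 573 probes at 2-fold or more had a partner at 2-fold or more the same way. Simulated unchanged genes with normally distributed noise of that SD passed 2-fold in 35.0% of cases and 4-fold in 5.51%. The SD was taken over all 612 genes, changed ones included, and the median absolute difference between 2 probes was 0.82. The simulated shares may therefore overstate those of unchanged genes in these data. With an SD of that size, many single genes near 2-fold are within probe error. At 4-fold or more, 734 genes were higher and 1010 lower. With values under the floor set to it (bounded values) 1997 genes were higher and 2023 lower by 2-fold.

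**Figure D1:**
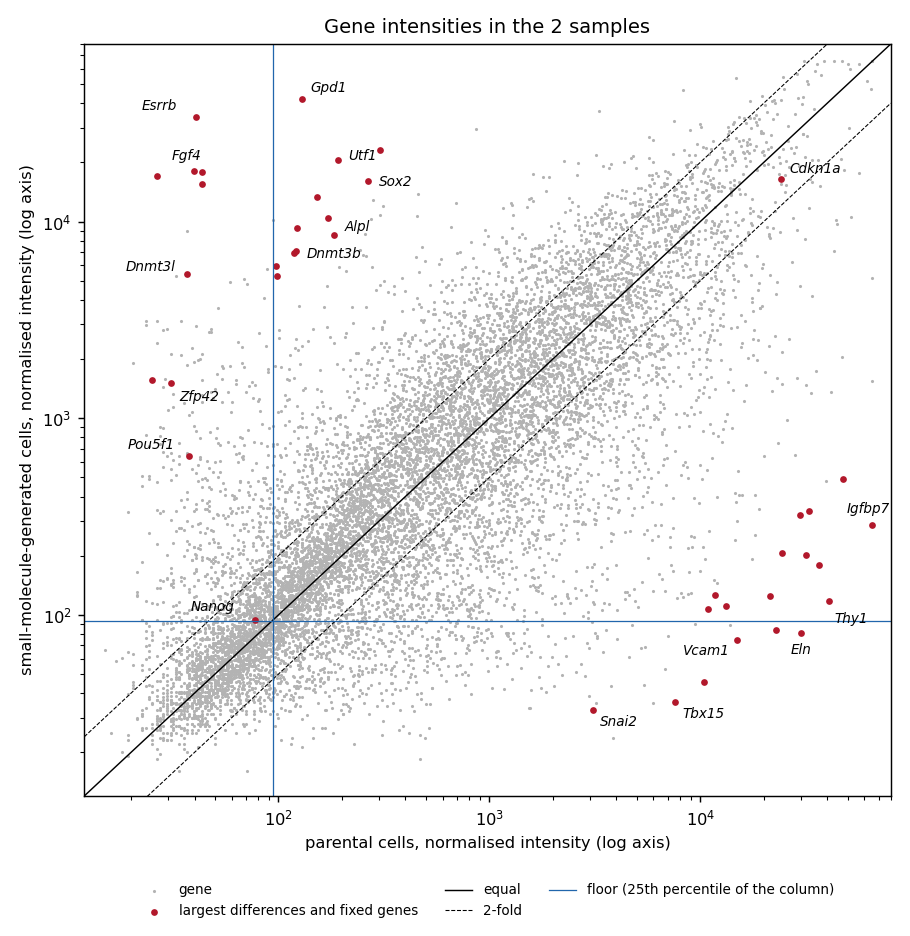
Normalised intensity of each of the 11484 genes in the parental cells (horizontal, log axis) and in the small-molecule-generated cells (vertical, log axis), 1 sample each. Dashed lines mark 2-fold and blue lines the floor of each sample (93.8 and 93.4); red points are the genes with the largest differences and those fixed in advance, with Esrrb (40.6 and 33968) at the upper left and Thy1 (40943 and 117) at the lower right.

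Of the 10 measured genes of the pluripotency core, 9 were 2-fold or more higher and none was lower. The list's median log2 difference was 5.75, or 4.95 with genes under the floor at their bound, and it lay at the 100th percentile of 10000 random lists of the same size and similar mean intensity. Dnmt3b, a de novo DNA methyltransferase, was 58.6-fold higher (121 and 7089). Fbxo15, an F-box gene of ES cells, was at least 190.0-fold higher (43.4 and 17816), and Zfp42, also known as Rex1, was at least 16.2-fold higher (30.8 and 1520). Pou5f1, which encodes OCT4, was under the floor in the parental cells at 37.8 and reached 639 in the small-molecule-generated cells, at least 6.82-fold higher. The exception was Nanog, read by 1 probe, which was under the floor in the parental cells at 77.7 and just above it in the small-molecule-generated cells at 94.7, so that its fold had only a lower bound, of 1.01.

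Genes of the naive state were higher as well. Of 15 measured members, 10 were higher, 1 was lower and 1 was dim, with a median log2 difference of 3.24 (100th percentile), or 2.37 with genes under the floor at their bound. Tfcp2l1, a transcription factor of naive ES cells, was at least 165-fold higher (43.4 and 15457), and Alpl, the alkaline phosphatase used as a stain for ES cells, was 46.8-fold higher (183 and 8563). Stat3, the transcription factor downstream of leukemia inhibitory factor, was the lower member, at 770.1 and 44.1, at least 8.24-fold lower. Its target Socs3 was at 2779 and 2670.2. Of 9 measured genes of the LIF, STAT3 and MYC list 3 were higher and 4 lower, and the median of -0.06 lay at the 34.8th percentile. Within it the kinase gene Jak2 was at least 13.8-fold lower (1286 and 47), whereas Pim1 was 14.2-fold higher (660 and 9358) and Mycn 11.2-fold higher (157 and 1758).

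Genes of the primed epiblast did not stand apart. Of 6 measured members 3 were dim, the TGF-beta family ligands Lefty1 (226 and 3055, 13.5-fold) and Lefty2 (36.7 and 390, at least 4.16-fold) were higher, and Sox4 was 6.41-fold lower (732 and 114). The median of 0.01 (-0.01 bounded) lay at the 49.4th percentile, and at the 99.8th when the dim members were left out. Germ cell genes were higher, with 7 of 8 measured members at 2-fold or more, or 5 bounded, and a median of 2.68 (2.21 bounded, 99.99th percentile). Tdrd12 (40.6 and 2928) was at least 31.2-fold higher and Piwil2 (40.6 and 862) at least 9.19-fold higher, both genes of the piRNA pathway. In the 2-cell stage list, 1 of 3 measured members was higher, Zfp352 by 3.45-fold (973 and 3354), while Eif1a was at 5974 and 6946, and the median of 0.22 lay at the 61.7th percentile. Of 9 measured genes of DNA methylation and demethylation 4 were higher and 2 lower (median 0.79, 92.4th percentile). Dnmt3l, the cofactor of the de novo methyltransferases, was at least 57.6-fold higher (36.7 and 5406), whereas Mbd2, a methyl-CpG binding protein, was 7.46-fold lower (2741 and 368).

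**Figure D2:**
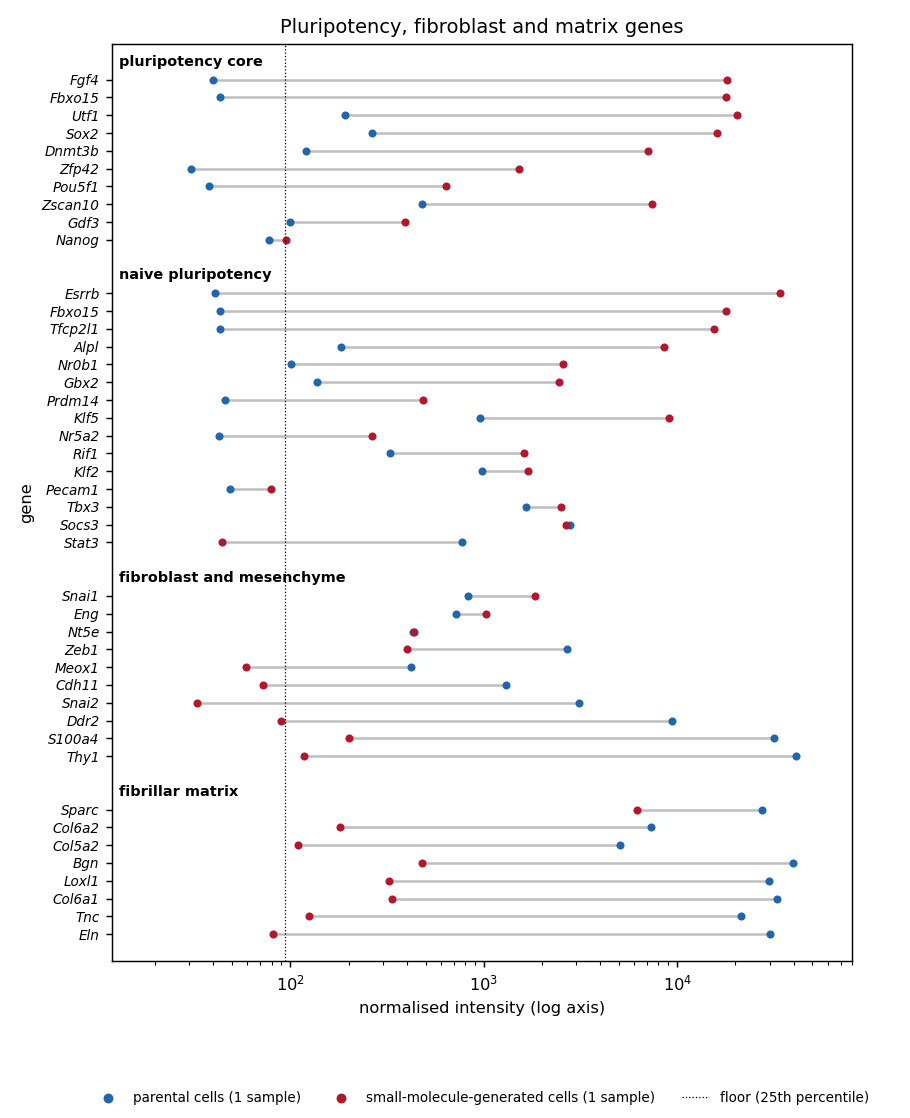
Normalised intensity (log axis) of each measured gene of the pluripotency core, naive pluripotency, fibroblast and mesenchyme, and fibrillar matrix lists in the parental and the small-molecule-generated cells, 1 sample each, joined by a line per gene. Sox2 stands at 265 and 16129 and Nanog at 77.7 and 94.7, while Thy1 stands at 40943 and 117.

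The matrix genes formed the list with the lowest median. All 8 measured members of the fibrillar matrix list were 2-fold or more lower in the small-molecule-generated cells, with a median log2 difference of -6.45 (percentile 0). Tnc, which encodes tenascin C, was 172-fold lower (21479 and 125), Col6a1, a chain of collagen VI, 97.8-fold lower (32937 and 337) and Loxl1, an enzyme that cross-links elastin, 91.9-fold lower (29755 and 324). Of 10 measured fibroblast and mesenchyme genes 7 were lower and 1 higher (median -3.50, -3.27 bounded, percentile 0). The calcium-binding protein gene S100a4 was 157-fold lower (31578 and 201), and Snai2, a transcriptional repressor of epithelial genes, was at least 33.1-fold lower (3095 and 32.8). Its paralog Snai1 went the other way, 2.20-fold higher (833 and 1833). Eng, which encodes endoglin, was at 715 and 1025. Genes of the TGF-beta response list were lower as well, 8 of 12 measured members with none higher (median -1.95, -1.76 bounded, percentile 0). That list was fixed with ligand, receptor and latent binding protein genes beside response genes, so its median does not read the response alone. The ligand gene Tgfb3 was at least 36.9-fold lower (3447 and 64.4) and Ltbp2, a latent TGF-beta binding protein, 37.6-fold lower (15264 and 406), while Tgfb2 was at 503 and 613.

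Markers of leukocytes were also brighter in the parental cells, beside these mesenchymal groups. Of 10 measured macrophage and leukocyte genes 6 were lower and 1 was higher in the small-molecule-generated cells, with a median of -1.80 (-1.29 bounded, percentile 0.04). C1qa, a complement component made by macrophages, was at least 34.2-fold lower (3198 and 35.7) and Fcer1g, an Fc receptor subunit, 9.17-fold lower (1894 and 206). Laptm5, a lysosomal protein gene of blood cells, was 9.48-fold higher (1287 and 12204), and the myeloid transcription factor gene Spi1 was at 224 and 268. Inflammation and chemokine genes went both ways, 4 of 9 higher and 3 lower. Their median of 0.88 (percentile 96.8, and 97.7 after intensity-dependent centring) rested on a gene dim in both samples, and the bounded median was -0.01 (percentile 42.7). The adhesion gene Vcam1 was at least 159.6-fold lower (14914 and 74.4) and the chemokine gene Cxcl12 119-fold lower (13234 and 111), whereas Icam1 was 6.09-fold higher (292 and 1779) and Saa3 5.25-fold higher (137 and 719). Of 9 measured interferon response genes 1 was higher, Bst2 by 3.94-fold (1264 and 4985), and 3 were lower, or 2 bounded, among them Irf7 by at least 3.52-fold (329 and 34.4). Their median was -0.49 (-0.24 bounded, percentile 7.78).

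Position and imprinting genes were lower in the small-molecule-generated cells. Of 16 measured Hox genes, which set position along the body axis, 11 were lower and none was higher (median -1.98, -1.81 bounded, percentile 0.01). Hoxc6 was 45.1-fold lower (5984 and 133) and Hoxb2 at least 29.0-fold lower (2711 and 56.6), while Hoxd13 (279 and 406) and Hoxd3 (347 and 486) differed by less than 2-fold. Of 19 measured imprinted genes 11 were lower and 4 higher, or 3 bounded (median -1.31, percentile 0.02). The growth factor gene Igf2 was 96.9-fold lower (47590 and 491), and Grb10, an adaptor of growth factor receptors, 24.9-fold lower (33371 and 1340.3). Phlda2 was at least 11.5-fold higher (81.7 and 1083) and Snrpn, a spliceosome component, 9.16-fold higher (384 and 3516).

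Beyond the lists, the largest differences among genes above the floor in both samples included Gpd1, the cytosolic glycerol-3-phosphate dehydrogenase, 324-fold higher in the small-molecule-generated cells (129 and 41805). The X-linked homeobox gene Rhox5 was 87.8-fold higher (152 and 13355), the oocyte-expressed gene Ooep 76.3-fold higher (122 and 9304) and Slc2a3, a high-affinity glucose transporter, 75.6-fold higher (304 and 22997). Bex1 (97.2 and 5978), Rpp25 (172 and 10432), Acsbg3 (118 and 6922) and Zfp296 (98.0 and 5316) were 61.5-fold, 60.7-fold, 58.4-fold and 54.2-fold higher. Fam25c was under the floor in the parental cells (26.4) and at 17001 in the small-molecule-generated cells, at least 181-fold higher. Igfbp7, a secreted binding protein of growth factors, was measured at 65303 and 285. Its parental value was close to the scanner's ceiling, so it was at least 229-fold lower. Cav1, the main protein of caveolae, was 203-fold lower (36558 and 180), Cdk5r1, an activator of the kinase CDK5, 119-fold lower (24534 and 206), the receptor kinase gene Axl 101-fold lower (10843 and 108) and Wls, needed for Wnt secretion, 92.9-fold lower (11721 and 126). To the floor went Timp3, an inhibitor of metalloproteinases, at least 245-fold lower (22868 and 83.7), and the transcription factor genes Irx1, at least 111-fold (10389 and 45.7), and Tbx15, at least 81.6-fold (7626 and 36.2).

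Epithelial genes were higher in part. Of 12 measured members 6 were higher and 1 was lower, with a median of 0.73 at the 96th percentile (95.99), inside the middle 95% of random lists, and outside it at 98.1 when dim members were left out. Epcam, an epithelial adhesion molecule also borne by ES cells, was at least 16.7-fold higher (25.2 and 1571) and the tight junction gene Cldn6 at least 43.7-fold higher (85.2 and 4098). Tjp1, a scaffold of tight junctions, was 2.74-fold lower (1924 and 702). Of 10 measured keratinocyte genes 3 were higher, 1 was lower and 3 were dim (median 0.26, -0.01 bounded, percentile 74.4), with Sfn, the 14-3-3 sigma gene, 38.2-fold higher (313 and 11959) and Krt10 2.24-fold lower (1245 and 557).

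Genes of DNA replication were higher and those of mitosis were not. Of 17 measured S phase genes 9 were higher and 1 lower, or 0 lower bounded (median 1.02, percentile 99.52). Chaf1b, a subunit of the chromatin assembly factor, was 7.62-fold higher (770.1 and 5867) and Ccne1, which encodes cyclin E1, 5.66-fold higher (610 and 3454). Of 12 measured G2/M genes none was higher and 3 were lower (median -0.13, percentile 30.2), among them Mki67, the proliferation marker, by 2.5-fold (2014 and 807). Of 10 measured genes of senescence and p53 4 were lower and 1 higher (median -1.19, -0.73 bounded, percentile 0.25), a shift that lay inside the random range (percentile 4.31) when lists were matched on the parental value. Cdkn2b, which encodes the cell cycle inhibitor p15, was 67.6-fold lower (8316 and 123) and Gadd45a 8.82-fold lower (3277 and 372), while the p21 gene Cdkn1a was at 24101 and 16492, a 1.46-fold difference. Of 18 measured chromatin regulators 7 were higher, or 6 bounded, and 1 lower (median 0.75, 0.58 bounded, percentile 97.4), just inside the random range, and outside it at 98.5 with matching on the parental value. The Polycomb genes Cbx7 (260 and 6686, 25.7-fold) and Jarid2 (376 and 2540.0, 6.75-fold) were higher, whereas Suz12 was 2.04-fold lower (2037 and 1001).

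Several lists of differentiated lineages had higher medians in the small-molecule-generated cells. Of 12 measured neuronal genes 6 were higher and 1 lower (median 0.83, 0.78 bounded, percentile 97.7), with the neurofilament gene Nefl at least 7.08-fold higher (36.7 and 664), Stmn2, a regulator of microtubules in neurons, 12.6-fold higher (206 and 2602) and Map2 4.15-fold lower (395 and 95.3). Neural progenitor genes had 4 of 12 higher, or 3 bounded, and 1 lower (median 0.73, 0.28 bounded, percentile 98.4), with Sox2 among the higher ones, Sox1 at least 2.79-fold higher (44.8 and 262) and Zic1 at least 55.8-fold lower (5213 and 68.0). Endothelial genes had 5 of 12 higher, or 4 bounded, such as Vwf by at least 7.05-fold (36.7 and 661), and 2 lower, Flt1 by at least 7.39-fold (691 and 63.8) and Plvap by 6.41-fold (17942 and 2798), with a median of 0.73 (0.54 bounded, percentile 98.0). Erythroid genes had 3 of 4 higher, or 2 bounded (median 1.37, 0.77 bounded, percentile 99.2), among them the embryonic globin genes Hbb-bh1 by at least 4.47-fold (92.6 and 419) and Hba-x by 2.78-fold (371 and 1032). Trophoblast genes also had 3 of 4 higher, or 2 bounded (median 1.48, 0.86 bounded, percentile 98.9), with Ascl2 at least 3.58-fold higher (39.7 and 336). With matching on the parental value these 5 lists lay inside the random range, at percentiles 96.9, 92.2, 96.9, 89.8 and 92.5. Bounded values put the neural progenitor, endothelial and trophoblast lists inside it as well, at 94.9, 96.5 and 92.4.

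Other lineage lists lay inside the random range. Mesendoderm and cardiac genes had 3 of 10 higher (median 0.49, 0.29 bounded, percentile 89.0), with Myl7, an atrial myosin light chain, at least 9.58-fold higher (27.6 and 898). Endoderm genes had 1 of 6 higher, 3 dim and 1 lower, the latter being Gata6, 12.2-fold lower (1733 and 142). Their median of 0.62 (percentile 93.3) rested in part on a dim gene and was -0.01 bounded. Muscle genes had 2 of 7 higher and 1 lower, or 1 and 0 bounded (median 0.11, percentile 60.0), with Tnnt1, a slow skeletal troponin, at least 18.9-fold higher (89.0 and 1776). Bone and cartilage genes had 2 of 6 higher and 2 lower, or 1 lower bounded (median 0.24, 0.19 bounded, percentile 65.7), the cartilage collagen gene Col2a1 being 11.7-fold lower (4565 and 392). Glial genes had 1 of 3 higher, Cnp by 2.5-fold (639 and 1600), and a median of 0.96 (percentile 83.9). Adipocyte genes had 2 of 4 lower, Cebpa by at least 2.43-fold (227 and 44.9) and Lpl by 2.22-fold (2684 and 1209), and a median of -0.84 (-0.64 bounded, percentile 10.1).

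**Figure D3:**
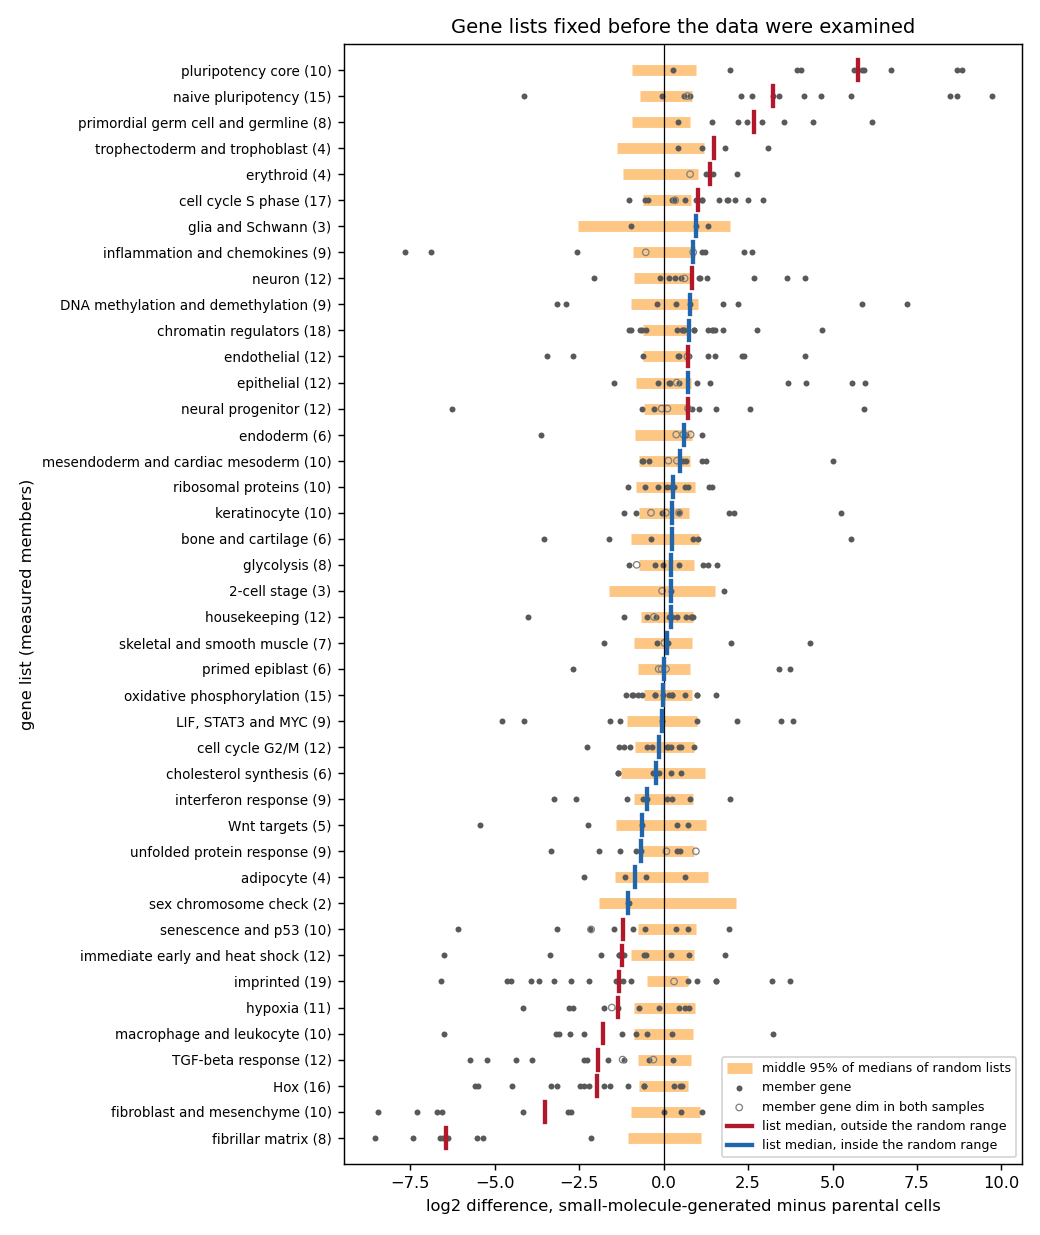
Log2 difference (small-molecule-generated minus parental cells) of each measured member of the 42 gene lists (points, open where dim in both samples), with each list's median (vertical bar) and the middle 95% of medians of 10000 random lists (orange). Medians ranged from -6.45 in the fibrillar matrix list to 5.75 in the pluripotency core, with 9 lists above and 9 below the random range.

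Immediate early genes were lower in the small-molecule-generated cells as a list. Of 12 measured immediate early and heat shock genes 7 were lower and 1 higher (median -1.24, -1.19 bounded, percentile 0.84), with Egr1, an early response transcription factor, 90.4-fold lower (17504 and 194), Zfp36 at least 9.49-fold lower (887 and 86.0) and the heat shock gene Hsph1 3.55-fold higher (1671 and 5927). Hypoxia genes had 5 of 11 lower, or 4 bounded, and none higher (median -1.35, -0.73 bounded, percentile 0.45), among them P4ha2, a collagen prolyl hydroxylase, at least 16.2-fold lower (1510 and 85.2) and Ndrg1 6.97-fold lower (2565 and 368). With an offset of 50 added before the logarithm the hypoxia list lay inside the random range, at percentile 2.82, as it did with bounded values, at 3.26. The unfolded protein response had 3 of 9 genes lower and none higher (median -0.67, percentile 3.06, 1.5 with the offset and 1.19 bounded), with Ddit3, which encodes CHOP, 9.96-fold lower (4571 and 459) and Atf4 at 10148 and 14144. Of 5 measured Wnt targets 2 were lower, Lgr5 by 43.1-fold (6577 and 153) and the cyclin gene Ccnd1 by 4.68-fold (2594 and 555), and the median of -0.65 (-0.38 bounded) lay at percentile 12.6.

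Metabolic and reference genes moved little as groups. Glycolysis had 3 of 8 genes higher and 1 lower (median 0.23, percentile 53.03), with the hexokinase gene Hk2 3.0-fold higher (4382 and 13142) and Tpi1 at 61581 and 51562. Ldha was lower by 2.04-fold on average (14101 and 6901), but its 3 probes ranged from -1.95 to 0.31 in log2 difference and its brightest probe gave 0.31, the opposite sign. Oxidative phosphorylation had 1 of 15 genes higher, Uqcrc1 by 2.93-fold (5902 and 17309), and 1 lower, Uqcrc2 by 2.14-fold (14184 and 6614), with a median of -0.03 (percentile 25.2). Cholesterol synthesis had 2 of 6 lower, Lss by 2.55-fold (1677 and 657) and Cyp51 by 2.54-fold (3723 and 1465) (median -0.22, percentile 29.0). Ribosomal protein genes had 2 of 10 higher and 1 lower, or 0 lower bounded (median 0.27, percentile 60.4), with Rpl8 2.56-fold higher (9694 and 24783). Among 12 measured housekeeping genes 2 were lower and none higher (median 0.21, percentile 56.8), among the lower ones B2m, the light chain of class I histocompatibility antigens, 16.3-fold lower (24338 and 1497). Of the sex chromosome genes, Xist was at 109 and 53.1 and the Y-linked Kdm5d at 292 and 142 (median -1.04, -0.63 bounded, percentile 12.7).

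**Figure D4:**
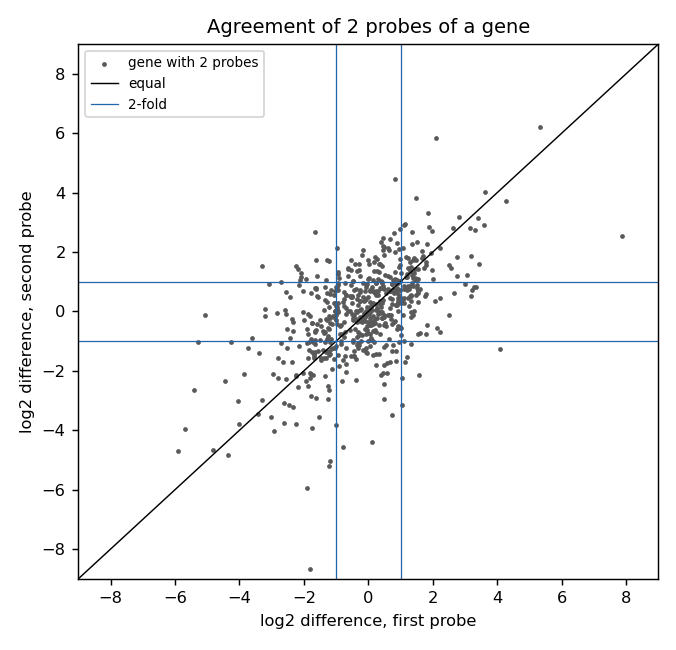
Log2 difference (small-molecule-generated minus parental cells) of the first and the second probe of each of 612 genes with 2 probes above the floor, 1 point per gene. The correlation between the probes was 0.545, and 1 probe's SD around its gene was 1.05.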

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

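The comparison of probes without a gene name was chosen after the data were seen. The 1609 probes that the annotation does not list entered no comparison of genes. Of these, 983 were above the floor in at least 1 sample, and 197 were 2-fold or more higher in the small-molecule-generated cells than in the parental cells, while 117 were lower. The shares were 20.04% higher and 11.9% lower, against 22.5% and 23.1% among named probes. The largest difference upward was at probe mMC018853, at 30.8 and 19703, and the largest downward at PH_mM_0007519, at 9788 and 133. No biological explanation was tested for these probes.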

How the results depend on the processing

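The probe error size rule, the setting of low values to the floor and the centring of probe classes were chosen after the data were seen. The counts of 2159 higher and 2209 lower genes stayed within 1.5 times under the other filters, normalisations and probe rules. Quantile normalisation (2150 and 2216) could change little, because both columns already had nearly the same quantiles. The counts were 734 and 1010 at 4-fold and 664 and 940 at 2 SD of the probe error. There 42.1% and 41.4% of the called genes were higher, against 49.4% at 2-fold. Fewer genes pass a larger size by construction. The correlation of 0.704 was 0.787 without a filter on dim genes and 0.539 over genes above the median. The calls of the pluripotency core, naive, germline, S phase, fibroblast, matrix, Hox, TGF-beta, macrophage, imprinted and immediate early lists held under every alternative run. Low signal limits the folds of at least 1065 of the called genes, which went from or to the floor and have bounds only. The floor is a percentile of the column and not a measured background. Folds that rest on a value just above it may be limited too. Examples are Bex1 (97.2 in the parental cells, 61.5-fold higher) and Axl (108 in the small-molecule-generated cells, 101-fold lower). No paired analysis was possible because each group had 1 sample.

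Percentiles that crossed the limits of the random range were as follows, and the cause was not tested. With matching on the parental value they were 98.5 for chromatin regulators, 98.0 for inflammation, 4.31 for senescence and p53, 89.8 for erythroid, 96.9 for neuronal, 92.2 for neural progenitor, 92.5 for trophoblast and 96.9 for endothelial genes. Without dim members, the primed epiblast list was at 99.8, endothelial 95.6, erythroid 94.6, neural progenitor 94.3, senescence and p53 3.26 and epithelial 98.1. With an offset of 50, chromatin regulators were at 98.0, endothelial genes at 96.5, hypoxia at 2.82 and the unfolded protein response at 1.5. With low values set to the floor, the unfolded protein response was at 1.19, hypoxia at 3.26, neural progenitor at 94.9, trophoblast at 92.4 and endothelial at 96.5, and the erythroid median was 0.77 instead of 1.37. Medians that this setting also moved by over 1.5 times were 0.86 for trophoblast instead of 1.48, 0.28 for neural progenitor instead of 0.73, -0.73 for hypoxia instead of -1.35, -0.73 for senescence and p53 instead of -1.19, 0.29 for mesendoderm instead of 0.49, -0.38 for Wnt targets instead of -0.65 and -0.24 for interferon response instead of -0.49. Inflammation (0.88), endoderm (0.62), keratinocyte (0.26) and primed epiblast (0.01) medians were each -0.01. With probe classes centred, neuronal genes were at 97.1 and epithelial genes at 98.3. Chromatin regulators were at 97.6 after quantile normalisation and 98.0 with 5 bins, and inflammation was at 97.7 after lowess. The sex chromosome median of -1.04, over 2 genes, was -1.11 when centred on the median, -1.05 after lowess, -0.73 with the offset, -0.63 with low values at the floor and -1.20 with probe classes centred. Ldha was reversed with its brightest probe, 0.31 against -1.03. Of the other log2 differences of named genes, 1156 values were the same within the probe error and 47 moved, 21 with the offset and 26 with low values at the floor.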

Other observations

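The comparison of gene families by symbol, the genes named here, the tests of single probes and of an intensity-dependent shift, and every bounded value were chosen after the data were seen. The tests of the second leukocyte and neuronal lists and of low values in the neuronal list were set down before their results were seen. Of 141 symbol families with at least 8 measured members, 5 had medians outside the middle 99% of random lists, where 1.41 would if genes varied independently. Collagens had 14 of 21 members 2-fold or more lower in the small-molecule-generated cells and 1 higher (median -2.12, percentile 0). Without the 5 that stand on a fixed list, 9 of 16 were lower, or 8 with values under the floor bounded, and the median was -1.43 (-1.29 bounded, percentile 0.02). The basement membrane chains Col4a1 (28276 and 650) and Col4a2 (31783 and 1483) were 43.5-fold and 21.4-fold lower. Col9a2, a collagen of cartilage, was the higher member, by at least 13.3-fold (80.7 and 1250), and Col18a1 was at 8787 and 11529. Carbohydrate sulfotransferases, which sulfate the sugar chains of matrix proteoglycans and other glycans, had 6 of 10 members lower, or 5 bounded, and 1 higher (median -1.68, -1.32 bounded, percentile 0.13). Chst14, the dermatan 4-O-sulfotransferase, was at least 16.8-fold lower (1574 and 64.4) and Chst8 at least 8.08-fold higher (57.8 and 758).

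Sorting nexins, proteins of endosomal sorting, had 14 of 26 members lower and 1 higher (median -1.13, percentile 0.02). Snx7 was at least 16.6-fold lower (1553 and 33.7) and Snx24 16.3-fold lower (1983 and 122), whereas Snx10 was 2.75-fold higher (1300 and 3574). The Snord class, named for small nucleolar RNAs that guide methylation of ribosomal RNA, had 7 of 13 members higher and 2 lower, or 1 lower bounded. Its median was 1.36 (1.06 bounded, percentile 99.9), with Snord33 at 368 and 1147 and Snord95 at 68.0 and 618. Whether these probes read the small RNAs or longer transcripts was not tested, nor whether the members vary independently. Genes named for a coiled-coil domain (Ccdc) share no common function, and 21 of 69 were higher, or 18 bounded, and 7 lower. Their median was 0.59 (0.37 bounded), at percentile 99.8 (97.8 bounded). With low values at the floor the Ccdc genes thus lay inside the middle 99%, and the other 4 families stayed outside it under that setting, after lowess centring and with probe classes centred. Low values at the floor also put the olfactory receptor genes (Olfr) at percentile 99.88 and predicted genes (Gm) at 99.84, outside the middle 99%, from 96.91 and 98.88.

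Leukocyte genes were lower in the small-molecule-generated cells, and a candidate explanation is that the parental cells held leukocytes. A second list of 48 leukocyte genes, which shares no member with the first, had 25 measured, 10 lower and 1 higher. Its median of -0.81 lay at percentile 0.1. That median was the value of Ms4a6c, a gene dim in both samples (89.8 and 51.2), and the bounded median was -0.34 (percentile 1.68). Some calls had bounds under 2-fold, such as Cd84, at least 1.69-fold lower, and Csf2rb, the higher member, at least 1.04-fold. Within the second list Arhgdib (10011 and 575), Msr1 (884 and 111), Fcgr3 (505 and 75.8) and Trem2 (373 and 26.1) were lower. Ifi30 (4060 and 5188), Coro1a (1008 and 551) and Lcp1 (744 and 1401) were not 2-fold lower. An intensity-dependent shift between the columns is argued against by the first list's percentile of 0.04, since its random lists were matched on mean intensity. Lowess centring left that list's median at -1.85, from -1.80, below the uncentred random range, which began at -0.88. It adds little, because it moved the median of all genes only from 0.07 to 0.02. How many of these genes the parental cells express themselves was not tested, and different expression by the cells, passage and medium stay open.

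Neuronal genes were higher in the small-molecule-generated cells at the 97.7th percentile. Values near the floor stay open as a source: the list lay at percentile 98.2 with low values set to the floor, past the limit set for excluding them, but matching on the parental value, where low starting values are shared with the random lists, put it inside the range at 96.9. With probe classes centred it was at 97.1. Neurons among the cells and expression by the stem cells themselves cannot be told apart here, since either could raise a second list of neuronal genes. That second list of 50 genes, 31 measured, lay inside the random range at percentile 96.55, between the limits set for and against neurons. It lay outside the range at 99.57 with values under the floor bounded. It had 12 higher and 3 lower members, among them Uchl1 (2596 and 17243) and Celf5 (267 and 1979) higher and Dpysl3 (1438 and 93.4) lower.

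Stat3 and Jak2 were under the floor in the small-molecule-generated cells and above it in the parental cells. An error of single probes may account for either reading. Among 192 probes at 4-fold or more, 35.9% had a partner probe of the same gene with no 2-fold call the same way. The unbounded log2 differences of Stat3 (-4.13) and Jak2 (-4.77) were well past 4-fold, and the share was not computed for differences of that size. It was 48.7% among the 573 probes at 2-fold or more and so fell with size. For differences as large as these it may be lower than 35.9%. A partner without a call may itself be the probe in error, so the share is not an error rate for these probes. Both genes have 1 probe here, so probe error and expression cannot be told apart.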
